A study of Mus musculus with 6 samples.

How the data were processed

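The study measured messenger RNA in dorsal root ganglia (DRG, the clusters of sensory neuron cell bodies beside the spinal cord) of lumbar levels 4 to 6 from male C57bl/6 mice aged 8 to 10 weeks. An adeno-associated virus (AAV, a gene delivery vector) carrying GFP alone or leptin together with GFP had been injected into the sciatic nerve on both sides 4 weeks before the dorsal columns of the spinal cord were cut. Tissue was taken 24 hours after that injury. Per the labels' protocols, the ganglia were dissociated with dispase, collagenase and papain, the cells were passed over an albumin gradient to enrich neurons, RNA was isolated on silica columns, and stranded libraries were made from polyadenylated RNA. Each group has 3 libraries. The labels do not say whether each library came from a separate animal or from pooled animals, so the p-values measure the spread between these libraries, part of which may be technical.

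The authors deposited TPM values, which give each transcript's length-corrected share of a library on a scale that sums to 1000000, one value per Ensembl transcript and library. Per the submitters' processing notes, FastQC 0.11.9, Trim Galore 0.6.6, Salmon 1.6.0 and DESeq2 1.34.0 were used, with no role or order given, and the genome builds named are GRCm38 and mm10. The annotation release is not given in the sources used here. Of 140789 transcript identifiers, 97.4% occur in GENCODE M21, an annotation of GRCm38, but the version suffix is the same for 37 of them. The values therefore come from another release. Coordinates below were looked up by gene identifier in GENCODE M21 on GRCm38, and transcript classes (protein-coding, retained-intron) and lengths were looked up by transcript identifier in the same release.

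TPM keeps no record of the number of reads, so the depth of each library is unknown, and no counting intervals or detection limits are given. TPM is also a share of a fixed total, so a group of abundant transcripts that takes more of it lowers the values of the rest. Salmon divides reads among transcripts that share sequence. Values are therefore uncertain for close paralogs such as the tubulins Tuba1a, Tubb2a and Tubb3, the haemoglobin genes, the class I histocompatibility genes H2-D1 and H2-T23, ribosomal protein genes with processed pseudogenes, mitochondrial genes with nuclear copies, and small RNA genes inside larger genes. Genes used by every cell were not listed at 0 in any library: over Actb, Gapdh, Rplp0, Eef1a1, Ppia and Hprt, the lowest value was 357.7 TPM, for Rplp0.

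Transcript TPM were summed by gene identifier, which gave 54309 genes. Symbols are those that the authors paired with the identifiers, and 31 of the tested genes have none. The 15108 genes with a mean of at least 1 TPM over all 6 libraries were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (moderated test with a mean-variance trend, AAV-Leptin-GFP minus AAV-GFP, two-sided, no covariates). Tables were read with data.table (version 1.17.8), and plots were drawn with Python 3.11.15 and matplotlib 3.10.9. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low values. A gene was called higher or lower at a Benjamini-Hochberg adjusted p under 0.05. An adjusted p printed for a gene is limma's, and one printed for a gene list is from camera in limma unless another test is named.

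Fixed lists of genes for the tissue, the injury and the treatment, 41 in all, were tested against all other tested genes with camera (preset correlation between genes 0.01) when at least 5 members were tested, which held for 39 lists. Each list was also tested with the correlation estimated from the data, and with fry, which asks whether the genes of a list move on balance in one direction and does not compare them with other genes. The lists hold 864 different genes, of which 855 were matched by symbol and 751 were tested. Some genes are in several lists. A symbol with several gene identifiers counts once per identifier, so the glycolysis list of 20 genes has 21 tested members. The tests, lists, alternatives and rule for named genes were fixed before the data were examined. The rule took Lep and Lepr, the 12 largest increases and 12 largest decreases among called genes whose groups did not overlap (all of them where fewer passed), the 4 members with the smallest p of each list past the threshold, from each other list up to 3 called members or else the member with the smallest p, and Socs3, Stat3, Atf3, Jun, Sox11, Gap43, Sprr1a and Gal. It named 104 genes, some of which are not reported here. Single values per library were compared with exact permutation tests, which cannot go below p = 0.1 for 3 against 3 libraries.

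On simulated data for these 15108 genes and 6 libraries, with 100 genes changed by a log2 fold change of 1 and 100 by 2, the gene test recovered 83 and 89 of them with the right sign and made 7 false calls. None of 20 unchanged simulated lists was called. The simulated genes were drawn independently of each other, whereas correlations estimated in the real lists reached 0.73 (cholesterol biosynthesis genes). The simulation therefore cannot show how often the gene test or the list test makes false calls in these data. The gene test was not tried on log2 fold changes smaller than 1. The alternatives tried were another pseudocount, no filter and a stricter filter on low values, median-of-ratios scaling, quantile normalization, removal of mitochondrially encoded genes, no variance trend, array weights, the replicate number as a block, an adjusted p under 0.1, and leaving out each library in turn. Summing protein-coding transcripts only, a loess correction for GC content and transcript length, and a filter on the AAV-GFP libraries alone for the retained-intron comparison were added after seeing the data.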

Results

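The data are TPM values of 6 RNA-seq libraries from neuron-enriched L4 to L6 DRG cells of mice with a dorsal column axotomy, 3 libraries from animals given AAV-GFP and 3 from animals given AAV-Leptin-GFP. Dorsal column axotomy cuts the central branch of the sensory axons, which regrows poorly, and leptin is an adipose hormone that acts through the receptor Lepr and the JAK-STAT pathway. The comparison asks what leptin delivered to sensory neurons did to gene expression 24 hours after the injury. The AAV-GFP libraries listed 60572, 55476 and 55954 transcripts above 0, and the AAV-Leptin-GFP libraries 64423, 64087 and 61474. Genes at 1 TPM or more numbered 14790 ± 67.9 (SD, n = 3) with AAV-GFP and 15221 ± 67.2 with AAV-Leptin-GFP. Pearson correlations of log2(TPM + 1) across genes were 0.982 to 0.984 within AAV-GFP, 0.978 to 0.981 within AAV-Leptin-GFP and 0.974 to 0.982 between the groups. Read depth is unknown. Values below are means ± SD over the 3 libraries of a group.

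The delivered gene, Lep (ENSMUSG00000059201, chromosome 6, 29060220 to 29073877 on GRCm38), was listed at 0 in all 3 AAV-GFP libraries and at 0.751, 0.547 and 3.56 TPM in AAV-Leptin-GFP replicates 1, 2 and 3. The sequence of the delivered gene is not given in the sources used here, and TPM of Lep count only reads that match the mouse reference transcripts, so a vector with an altered leptin sequence would be undercounted. An exact two-sided permutation test gave p = 0.1, the smallest value this design allows. Most of the signal was listed on a protein-coding transcript of 420 nt (0.659, 0.476 and 3.32 TPM), and the 3259 nt transcript held 0.0918, 0.0709 and 0.243 TPM. Lep lay under the filter of the gene test because its mean over the 6 libraries was below 1 TPM, and with no filter its limma adjusted p was 0.278. Without AAV-Leptin-GFP replicate 3 the difference in log2(TPM + 1) was 0.72, against 1.21 over all libraries. Lepr, the leptin receptor (ENSMUSG00000057722, chromosome 4, 101717404 to 101815352), stood at 1.13 ± 0.441 TPM with AAV-GFP and 1.37 ± 0.239 TPM with AAV-Leptin-GFP, a log2 fold change of 0.17 (SE 0.20, limma adjusted p = 0.698).

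**Figure D1:**
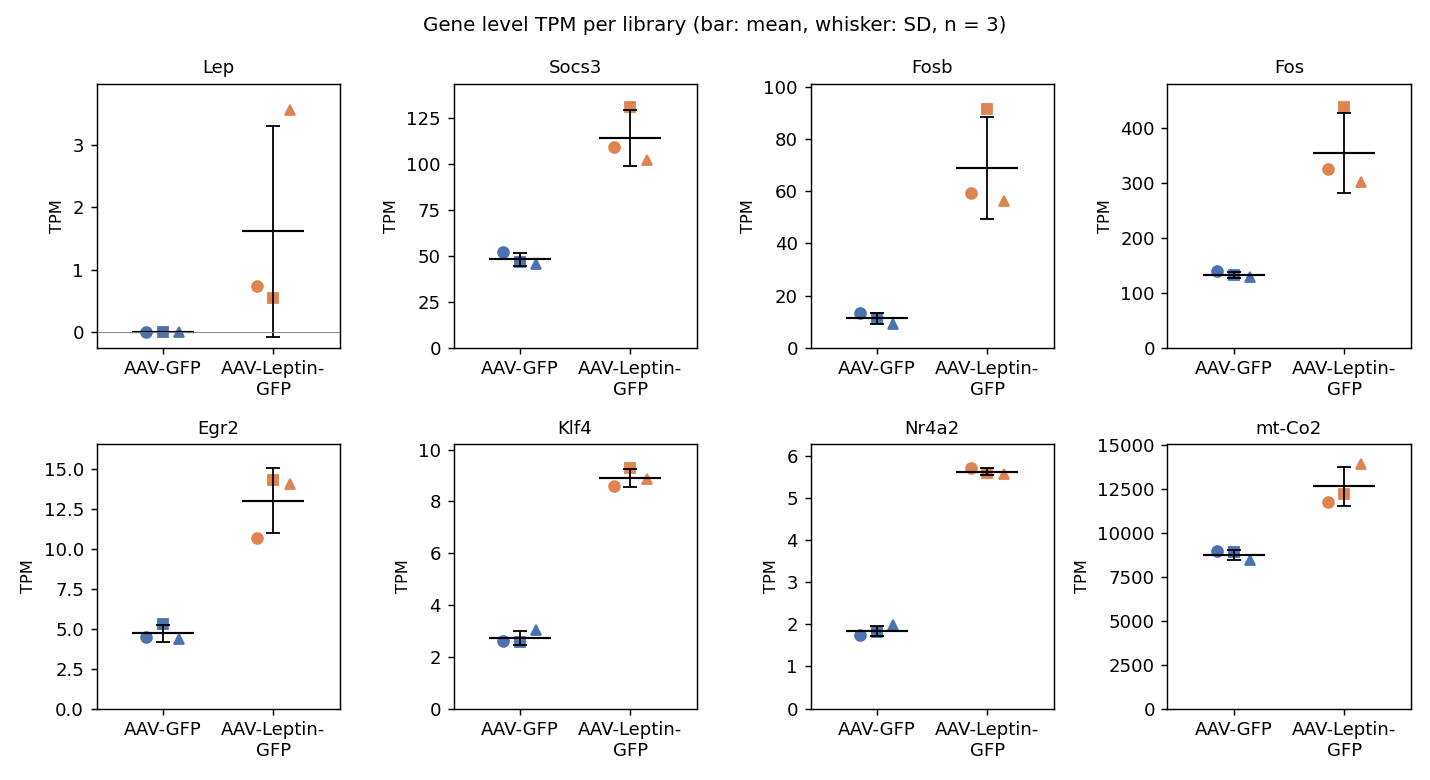
TPM of 8 genes (vertical axes, linear) in the AAV-GFP and AAV-Leptin-GFP libraries, with replicates 1, 2 and 3 as circles, squares and triangles, the mean as a horizontal bar and the SD as a whisker (n = 3). Lep was listed at 0 in each AAV-GFP library, and the AAV-Leptin-GFP values of Socs3, Fosb, Fos, Egr2, Klf4, Nr4a2 and mt-Co2 all lay above those of AAV-GFP.

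Of 15108 tested genes, 233 were higher with leptin and 10 lower at a limma adjusted p under 0.05. The balance was more even at an unadjusted p under 0.05, with 1703 higher and 1237 lower, and the median log2 fold change over all tested genes was -0.00016. The median log2 fold change of the higher genes was 0.84 (range 0.32 to 3.76), and 99 of them reached 1. The 10 lower genes moved less, with a median of -0.23 (range -0.32 to -0.19). The groups did not overlap for any of the 243 called genes, which the threshold itself favours, so this is no separate evidence. Across all tested genes 25.2% had groups that did not overlap, where chance gives 10%. The number of calls changed with the libraries: it was 409 higher and 11 lower without AAV-GFP replicate 1, 3 and 1 without AAV-GFP replicate 2, 4 and 1 without AAV-GFP replicate 3, 10 and 0 without AAV-Leptin-GFP replicate 1, 18 and 0 without AAV-Leptin-GFP replicate 2, and 15 and 0 without AAV-Leptin-GFP replicate 3. Of the 243 called genes, 209, 3, 4, 7, 15 and 12 stayed past the threshold in these fits in that order. All 243 kept their sign at an unadjusted limma p under 0.05 in each fit, but they had been chosen on the same libraries. With no filter on low values, 4 genes were higher and 0 lower, and with protein-coding transcripts only the counts were 88 and 3.

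**Figure D2:**
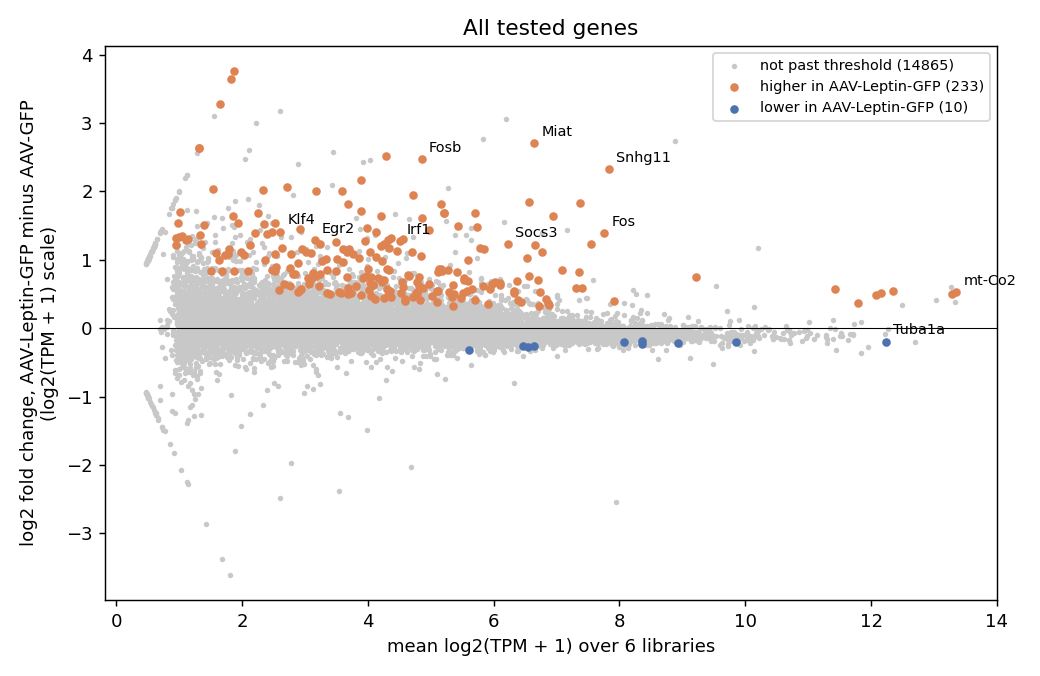
Log2 fold change (AAV-Leptin-GFP minus AAV-GFP, vertical axis) against mean log2(TPM + 1) over the 6 libraries (horizontal axis) for each of the 15108 tested genes. Orange points are the 233 genes called higher and blue points the 10 called lower, and the called-lower genes lie at high expression with changes between -0.32 and -0.19.

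Immediate early genes, the transcription factors and signalling regulators that cells induce first after a stimulus, were the group with the clearest increase. Of 22 tested members 15 rose (18 adjusted over the list alone), none fell, and the median log2 fold change was 0.94 (camera adjusted p = 2.6e-19, adjusted p = 0.369 with an estimated correlation, fry adjusted p = 0.00667). The AP-1 subunit gene Fosb (ENSMUSG00000003545, chromosome 7, 19302696 to 19310051) rose from 11.4 ± 2.13 to 68.9 ± 19.5 TPM (log2 fold change 2.48, SE 0.20, limma adjusted p = 0.00835). Its relative Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273) rose from 133 ± 5.66 to 354 ± 72.6 TPM (1.39, SE 0.13, adjusted p = 0.0143). The transcription factor genes Klf4 (1.41, SE 0.10, adjusted p = 0.00658) and Nr4a2 (1.22, SE 0.11, adjusted p = 0.0143) also rose, from 2.73 ± 0.263 to 8.91 ± 0.355 TPM and from 1.85 ± 0.123 to 5.63 ± 0.0781 TPM. The AP-1 family members Jun and Atf3 did not pass, Jun at 0.22 (adjusted p = 0.112) and Atf3 at 0.15 (adjusted p = 0.778). The number of members that rose was 14 without AAV-GFP replicate 1, 0 without AAV-GFP replicate 2, 1 without AAV-GFP replicate 3, and 2, 5 and 3 without AAV-Leptin-GFP replicates 1, 2 and 3, while 18 or 19 of the 22 were higher at an unadjusted limma p under 0.05 each time. With protein-coding transcripts only 15 rose, with a median of 0.91. With no filter on low values none of 25 passed and 20 were higher at an unadjusted p under 0.05.

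Socs3, the feedback inhibitor that leptin induces through STAT3 (ENSMUSG00000053113, chromosome 11, 117966079 to 117970047), rose from 48.0 ± 3.38 to 114 ± 15.1 TPM (log2 fold change 1.22, SE 0.10, limma adjusted p = 0.00835). Among JAK-STAT targets and feedback genes 4 of 25 tested members rose (8 adjusted over the list alone) and none fell: Socs3, Fos, Junb (0.71, adjusted p = 0.0268) and Cebpd (0.59, adjusted p = 0.0409). The list median was 0.07 (camera adjusted p = 0.00398, adjusted p = 0.534 with an estimated correlation), and it was 0.16 without AAV-GFP replicate 1 and 0.00021 without AAV-GFP replicate 2, where the list still passed. Fos and Junb are immediate early genes as well. Stat3 itself stood at 167 ± 6.70 and 163 ± 8.81 TPM (-0.03, adjusted p = 0.797), with a sign that flipped under quantile normalization and after removal of mitochondrially encoded genes. In the leptin receptor signalling list Socs3 alone of 19 tested members rose, and the list did not pass (median -0.014, mean 0.11, test direction up, camera adjusted p = 0.662). Leaving out AAV-GFP replicate 2, AAV-GFP replicate 3 or AAV-Leptin-GFP replicate 1 left 0 of the 25 JAK-STAT genes past the threshold, and leaving out AAV-Leptin-GFP replicate 2 or 3 left 2.

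The largest increases were mostly in non-coding RNA genes. The long non-coding RNA Miat (chromosome 5, 112213228 to 112229395) rose from 46.3 ± 34.2 to 257 ± 38.4 TPM (log2 fold change 2.71, SE 0.48, limma adjusted p = 0.0478). Mirg, a maternally expressed microRNA host transcript of an imprinted cluster, rose from 8.45 ± 6.36 to 46.2 ± 8.37 TPM (2.52, SE 0.42, adjusted p = 0.0405), and the small nucleolar RNA host gene Snhg11 from 114 ± 70.9 to 515 ± 88.8 TPM (2.33, SE 0.38, adjusted p = 0.0380). AAV-GFP replicate 1 was the highest AAV-GFP library in these 3 genes, with Miat at 84.1 TPM against 17.4 and 37.4. Gm12940 (2.17, adjusted p = 0.0229), Gm26532 (2.06, adjusted p = 0.0143) and Scarna13 (2.04, adjusted p = 0.0286), a small Cajal body RNA, rose too. The genes Mir8103, Snora31, ENSMUSG00002074943, SNORA2C and Mir8102 were listed at 0 in every AAV-GFP library, so no fold is given. Their means with AAV-Leptin-GFP were 12.6 TPM for Mir8103, 11.5 for Snora31, 9.84 for ENSMUSG00002074943, 5.37 for SNORA2C and 5.47 for Mir8102. TPM is corrected for length, so a few fragments can give such values in very short genes, and fragment numbers are unknown. Mir8103 (11.6, 12.2 and 13.9 TPM) and Snora31 (10.6, 11.2 and 12.7 TPM) kept the same proportion in AAV-Leptin-GFP replicates 1, 2 and 3. Their small spread may thus reflect equal low fragment numbers, and a value of 0 may be a missed transcript. Snora31 lies within the gene Tpt1 (chromosome 14, 75847905 to 75848034) and Mir8103 within Osbpl7 (chromosome 11, 97063768 to 97063874). Retained-intron transcripts, which still contain an intron, took 2.29% ± 0.200 of all TPM with AAV-GFP and 3.53% ± 0.260 with AAV-Leptin-GFP, 1.54 times as much (exact permutation p = 0.1, the smallest possible with n = 3). The adjusted p of Miat ranged from 0.00786 to 0.203 over 16 alternatives, past the threshold in 8.

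Genes of the mitochondrial genome were higher with leptin. Of 15 tested members 7 rose (13 adjusted over the list alone), none fell, and the median log2 fold change was 0.45 (camera adjusted p = 3.74e-11, adjusted p = 0.534 with an estimated correlation). The complex IV subunit mt-Co2 (chromosome M, 7013 to 7696) rose from 8755 ± 285.5 to 12622 ± 1121 TPM (0.52, SE 0.06, limma adjusted p = 0.0202), although under quantile normalization its fold change was 0.043. The others with the smallest p were cytochrome b, mt-Cytb (0.55, adjusted p = 0.0228), and the complex I subunits mt-Nd2 (0.57, adjusted p = 0.0269) and mt-Nd4 (0.52, adjusted p = 0.0301). Their share of all TPM was 5.88% ± 0.234 with AAV-GFP and 8.08% ± 0.949 with AAV-Leptin-GFP (exact permutation p = 0.1, n = 3). Leaving out AAV-GFP replicate 1 left 7 members past the threshold, and leaving out any other library left 0, with 11 to 13 at an unadjusted limma p under 0.05.

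**Figure D3:**
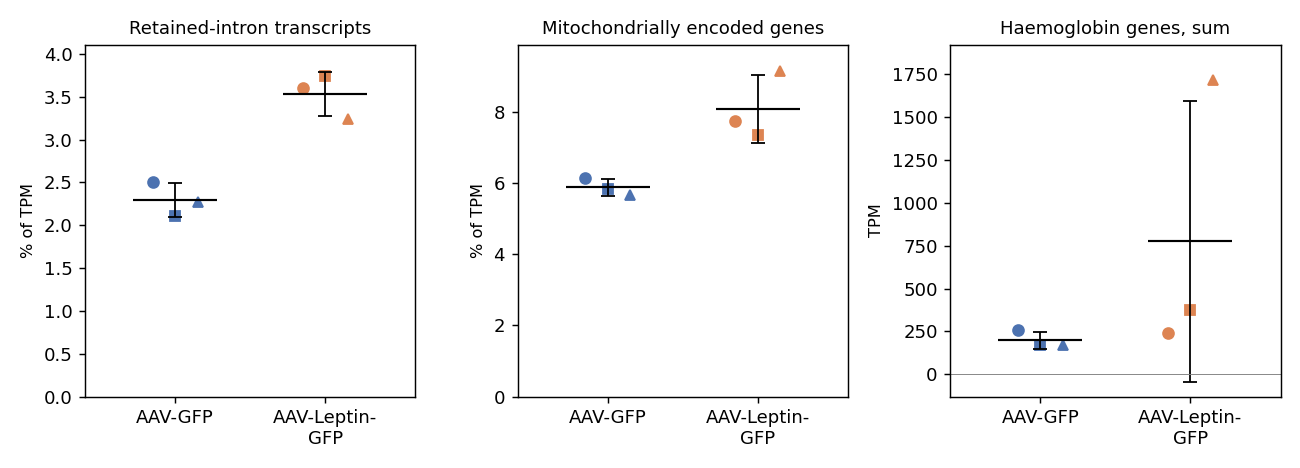
Share of TPM in retained-intron transcripts and in mitochondrially encoded genes (percent) and summed TPM of haemoglobin genes, per library, with replicates 1, 2 and 3 as circles, squares and triangles, means as bars and SD as whiskers (n = 3). Retained-intron shares were 2.29% and 3.53% on average, and the haemoglobin value of AAV-Leptin-GFP replicate 3 was 1718 TPM.

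The lists of ribosomal protein, nuclear oxidative phosphorylation, glycolysis and cholesterol biosynthesis genes passed downward with small medians, and of their members Ldha alone passed the test over all genes. No ribosomal protein gene passed the test over all genes (0 of 56; 25 lower and 1 higher adjusted over the list alone), but 53 had a log2 fold change below 0, and the list median was -0.14 (camera adjusted p = 8.94e-15, adjusted p = 0.534 with an estimated correlation). Rpl27 was at -0.21 (adjusted p = 0.0583), Rpl11 at -0.15 and Rpl19 at -0.20. All 40 tested nuclear oxidative phosphorylation genes lay below 0, with none past the test over all genes and 10 adjusted over the list alone (median -0.12, camera adjusted p = 2.06e-12, adjusted p = 0.534 with an estimated correlation). The values were -0.18 for Cox6a1, -0.14 for Cox5a, -0.22 for Ndufs6 and -0.17 for Ndufb9. At an unadjusted limma p under 0.05, 35 ribosomal protein genes were lower and 1 higher, and 22 oxidative phosphorylation genes were lower. Over both lists together the median was -0.133, and random lists of other genes matched on transcript length and expression had a median of -0.131, so these lists did not stand apart from genes of similar length and expression (percentile 45.2 of 10000). No other list was compared with matched genes, so the same is not excluded for the other lists that passed downward. Among 21 tested glycolysis genes Ldha, the lactate dehydrogenase A subunit, fell from 524 ± 16.4 to 449 ± 7.99 TPM (-0.22, SE 0.04, adjusted p = 0.0405), and 20 did not pass. Adjusted over the list alone, 4 glycolysis genes fell (13 members below 0 and 8 above, median -0.06, camera adjusted p = 0.00905, adjusted p = 0.534 with an estimated correlation). Tpi1 was at -0.16 (-0.70 with protein-coding transcripts only and -0.06 under quantile normalization), Aldoc at -0.17 and Pgam1 at -0.13 (-0.04 under quantile normalization). Cholesterol biosynthesis genes gave 0 of 23 past the test and a median of -0.10 (camera adjusted p = 0.0024, adjusted p = 0.711 with an estimated correlation), with Pmvk at -0.20, Fdps at -0.22, Mvd at -0.20 and Idi1 at -0.17. Without AAV-Leptin-GFP replicate 3 the cholesterol list no longer passed (median -0.04, camera adjusted p = 0.0976), while its median was -0.19 without AAV-Leptin-GFP replicate 2, and that of the glycolysis list -0.04 without AAV-GFP replicate 3. Quantile normalization ended the calls of the oxidative phosphorylation (median -0.06, camera adjusted p = 0.0503), glycolysis (-0.02) and cholesterol lists (-0.08), and gave ribosomal protein genes a median of -0.06 (camera adjusted p = 0.0165). A correction for GC content and transcript length, chosen after seeing the data, gave medians of -0.09 for ribosomal protein and -0.08 for oxidative phosphorylation genes, both still past the threshold.

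The 10 genes called lower had small changes and high expression, and whether a trend with expression level contributed was not tested. They were Snrpf, a core protein of the spliceosomal particles (-0.32, SE 0.05, limma adjusted p = 0.0405), the oligosaccharyltransferase subunit Ostc (-0.28), Serp2 (-0.26), the secreted factor Nenf (-0.26), the glutathione peroxidase Gpx1 (-0.23), Ldha, Vwa5a (-0.20), the ATP synthase component Atp5mpl (-0.20), the α-tubulin Tuba1a (-0.20) and the autophagy protein Gabarap (-0.19). Tuba1a (ENSMUSG00000072235, chromosome 15, 98949837 to 98953703) fell from 5143 ± 62.8 to 4489 ± 99.8 TPM (adjusted p = 0.0318) and was the 1 of 27 tested cytoskeleton and axonal transport genes to pass over all genes. That list had a median of -0.06 (camera adjusted p = 0.0018, adjusted p = 0.534 with an estimated correlation), which turned to 0.019 under quantile normalization, was -0.04 without AAV-Leptin-GFP replicate 3, and missed the threshold with protein-coding transcripts only (-0.02, camera adjusted p = 0.0697). Tubb2a stood at -0.17, Stmn2 at -0.14 and Tubb3 at -0.10. Each of the 10 genes was called in 3 to 7 of 17 alternatives. Tuba1a was called in 7, with adjusted p from 0.00848 to 0.216, and lost its call without any 1 of the 6 libraries. Under quantile normalization its value was -0.41, while those of Ldha (-0.14), Atp5mpl (-0.10) and Gabarap (-0.11) no longer passed.

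The lists of nociceptor, neuropeptide and pan-sensory-neuron genes passed downward with small medians, that of large-diameter sensory neurons did not, and no member of these lists passed alone over all tested genes. These lists were not compared with genes matched on transcript length and expression, so a trend with both may contribute. Adjusted over the list alone, 3 peptidergic, 0 nonpeptidergic, 4 neuropeptide and 4 pan-sensory-neuron members fell, and 1 large-diameter member rose. Peptidergic nociceptor markers, genes of the pain-sensing neurons that release neuropeptides, had 13 of 14 members below 0 and a median of -0.20 (camera adjusted p = 6.03e-04, adjusted p = 0.566 with an estimated correlation), which was -0.09 without AAV-Leptin-GFP replicate 3. Calca, which encodes the peptide CGRP, stood at 4141 ± 127.5 and 3235 ± 328.3 TPM (-0.36, adjusted p = 0.0603), Tac1, the substance P precursor, at -0.46 (adjusted p = 0.120), Calcb at -0.23 (adjusted p = 0.116) and the ion channel Trpa1 at -0.34 (adjusted p = 0.147). Neuropeptides and hormones, which share Calca, Calcb and Tac1 with that list, gave 0 of 21 and a median of -0.16 (camera adjusted p = 0.0024, adjusted p = 0.534 with an estimated correlation), which was -0.06 without AAV-GFP replicate 1 and -0.07 without AAV-Leptin-GFP replicate 2. Nonpeptidergic nociceptor markers gave 0 of 19 and a median of -0.16 (camera adjusted p = 0.00581, adjusted p = 0.711 with an estimated correlation), with Prkcq at -0.29, Mrgprb4 at -0.32, Plxnc1 at -0.20 and Cd55 at -0.16, and no longer passed without AAV-GFP replicate 1 (median -0.08, camera adjusted p = 0.196). Their median was -0.07 without AAV-Leptin-GFP replicate 3 (camera adjusted p = 0.0423). Pan-sensory-neuron markers gave 0 of 18 and a median of -0.07 (camera adjusted p = 0.00398, adjusted p = 0.534 with an estimated correlation), with Scg2 at -0.30. Quantile normalization ended the calls of the neuropeptide list (camera adjusted p = 0.0594) and the pan-sensory-neuron list (camera adjusted p = 0.704), whose median was -0.03 after removal of mitochondrially encoded genes (camera adjusted p = 0.0155). Large-diameter sensory neuron markers did not pass (0 of 20, 14 above 0, median 0.04, camera adjusted p = 0.616), and Whrn had the smallest p among them (0.33, adjusted p = 0.0629).

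**Figure D4:**
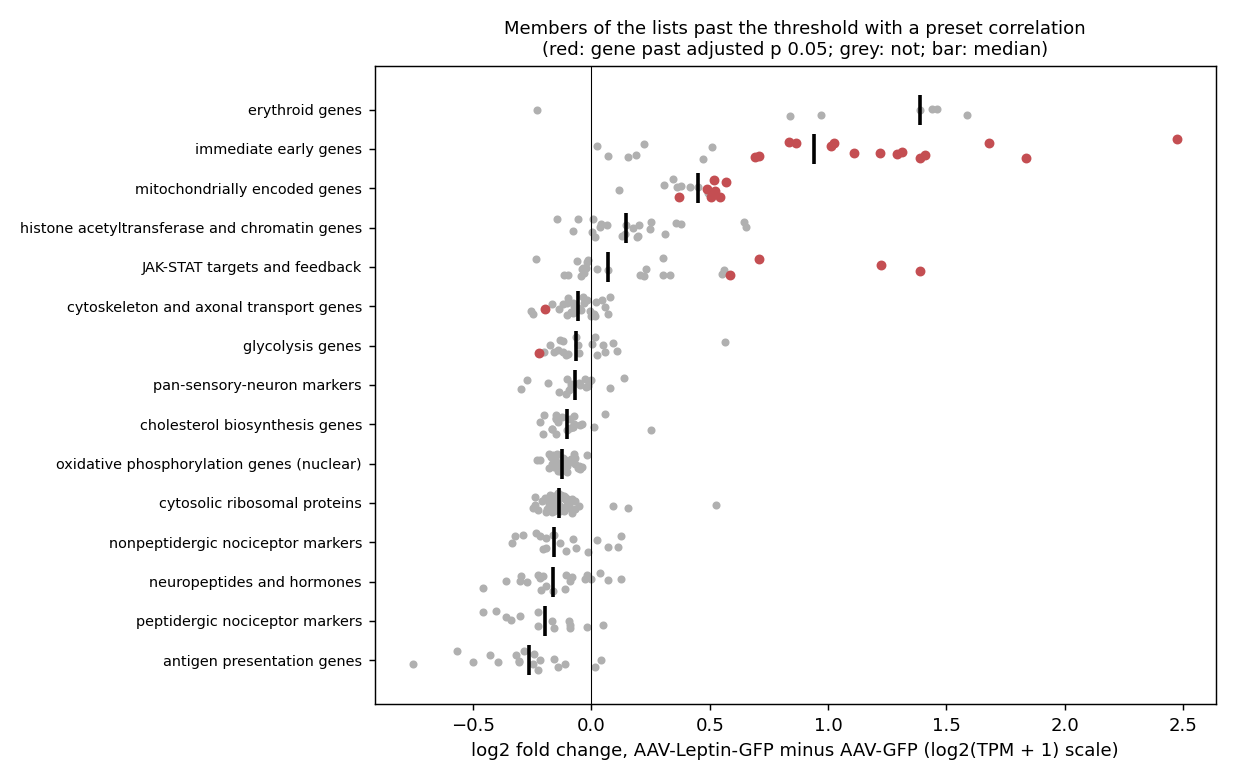
Log2 fold change (AAV-Leptin-GFP minus AAV-GFP, horizontal axis) of each tested member of the 15 gene lists past the camera threshold with the preset correlation. Red points are genes past a limma adjusted p of 0.05, grey points are not, and black bars are list medians, from -0.26 for antigen presentation genes to 1.39 for erythroid genes.

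Genes of the injury response, whose induction in sensory neurons goes with axon regrowth, did not pass as a list. Of 38 tested regeneration-associated genes 1 rose, Socs3, and 37 did not pass, with 26 below 0 and 12 above (median -0.11, camera adjusted p = 0.0665). The list passed downward without AAV-GFP replicate 3 (median -0.14, camera adjusted p = 0.0161) or AAV-Leptin-GFP replicate 1 (median -0.16, camera adjusted p = 7.26e-04), with no filter on low values (median -0.09, camera adjusted p = 0.0198) and after removal of mitochondrially encoded genes (median -0.08, camera adjusted p = 0.0309). Its median was -0.04 without AAV-GFP replicate 1 (camera adjusted p = 0.276) or AAV-Leptin-GFP replicate 3 (camera adjusted p = 0.255). Atf3 stood at 41.1 ± 8.89 and 46.8 ± 16.4 TPM. Gap43, a growth cone protein, stood at 310 ± 17.6 and 257 ± 24.0 TPM (-0.27, adjusted p = 0.113), Gal, the neuropeptide galanin, at -0.27 (adjusted p = 0.145), Sox11 at 0.31 (adjusted p = 0.355) and Sprr1a at -0.11 (adjusted p = 0.846). Axon growth and guidance genes (0 of 29, median 0.01, camera adjusted p = 0.739) did not pass, with Robo2 at -0.20. Histone acetyltransferase and chromatin genes passed as a list with 0 of 23 members past the test over all genes, 3 higher adjusted over the list alone and 20 of 23 above 0 (median 0.15, camera adjusted p = 0.00494, adjusted p = 0.534 with an estimated correlation). The smallest p among them were those of the histone demethylase Kdm6b (0.64, adjusted p = 0.0714), the deacetylases Hdac6 (0.36) and Hdac3 (0.20), and the methylcytosine dioxygenase Tet2 (0.65).

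Markers of other cell types that a DRG preparation can hold showed few changes. Erythroid genes passed as a list with 0 of 7 members past the test alone (median 1.39, camera adjusted p = 0.0379, adjusted p = 0.711 with an estimated correlation). Hbb-bt stood at 14.02 ± 4.73 and 54.3 ± 46.2 TPM, Hba-a1 at 1.46, Alas2 at 0.97 and Slc4a1 at 0.84. The haemoglobin genes summed to 256, 169 and 171 TPM with AAV-GFP and 238, 372 and 1718 TPM with AAV-Leptin-GFP. Without AAV-Leptin-GFP replicate 3 the erythroid median was 0.55 (camera adjusted p = 0.0513) and that of the immediate early genes 1.03. The erythroid list also missed the threshold without AAV-GFP replicate 1 (median 1.56, camera adjusted p = 0.0653), 2 (1.29, 0.0515) or 3 (1.33, 0.104). Antigen presentation genes passed downward with 0 of 18 alone (median -0.26, camera adjusted p = 0.00398, adjusted p = 0.711 with an estimated correlation), with Psmb9 at -0.50, Psmb8 at -0.57, H2-T23 at -0.75 and H2-D1 at -0.32, and not without AAV-GFP replicate 3 (median -0.09, camera adjusted p = 0.24). Their median was -0.47 without AAV-GFP replicate 2. None of the lists of satellite glia (median -0.09), Schwann cells and myelin (-0.11), macrophages (-0.09), neutrophils (0.27), endothelium (median 0.10, mean 0.05, test direction down), pericytes and smooth muscle (-0.07), fibroblasts and matrix (0.08), B and plasma cells (-0.15), adipocytes (0.24) or spinal cord glia (0.09) passed, with camera adjusted p from 0.0746 to 0.991. Without AAV-GFP replicate 2, neutrophil markers passed upward (median 0.59, camera adjusted p = 1.54e-06) and satellite glia downward (median -0.13, camera adjusted p = 0.00936). The fibroblast list passed upward without AAV-GFP replicate 1 (median 0.13, camera adjusted p = 0.0261) or AAV-Leptin-GFP replicate 1 (median 0.18, camera adjusted p = 0.0381). T and NK cell markers (3 tested, median -0.07) and skeletal muscle genes (4 tested, median 0.01) were too few to test. In the Schwann cell list Egr2 rose (1.29, adjusted p = 0.0155), a myelination factor that is also an immediate early gene, and in the spinal cord glia list the glutamate transporter Slc1a2 rose from 1.83 ± 0.188 to 5.04 ± 1.31 TPM (1.08, adjusted p = 0.0365). Dbi (-0.24), Cd14 (0.76), Mpo (0.68), Egfl7 (-0.22), Vtn (0.48), Fn1 (0.70), Ighm (0.36), Car3 (0.25), Lck (-0.15) and Acta1 (0.28) had the smallest p of their lists and did not pass.

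Among the other lists, interferon response genes had 1 of 27 members past the test, the transcription factor Irf1, which rose from 13.8 ± 2.70 to 34.6 ± 5.82 TPM (1.27, SE 0.16, adjusted p = 0.0238), while the list median was -0.20 (camera adjusted p = 0.0868). That list passed downward without AAV-GFP replicate 2 (median -0.32, camera adjusted p = 0.00936) or AAV-Leptin-GFP replicate 1 (median -0.53, camera adjusted p = 6.11e-07), with no filter on low values (camera adjusted p = 0.0375), after removal of mitochondrially encoded genes (0.0182) and with protein-coding transcripts only (0.0489). Its median was -0.13 without AAV-GFP replicate 3 (camera adjusted p = 0.395) and -0.08 without AAV-Leptin-GFP replicate 3 (camera adjusted p = 0.638). Of 22 PI3K-mTOR and growth factor signalling genes Tsc2, an inhibitor of mTORC1, rose (0.53, adjusted p = 0.0338), but on protein-coding transcripts only its value was 0.13 (adjusted p = 0.452). No member passed alone among heat shock genes (15 tested, median -0.020, mean 0.07, test direction down), unfolded protein response genes (22, median -0.0059, mean 0.01, down), synaptic vesicle genes (24, median 0.014, mean -0.014, down), fatty acid metabolism genes (25, median -0.03, mean 0.01, down), cytokines and chemokines (16, median 0.13), cell cycle genes (16, median 0.08) or immune checkpoint and complement genes (16, median -0.10). These lists, the signalling list (median 0.0041, down) and the voltage-gated ion channel list (26 tested, median 0.0012, mean 0.03, down) had camera adjusted p from 0.364 to 0.998. Among the lists with no member past the test, those with the smallest p were Hspe1 (-0.15), Sel1l (0.12), Syp (-0.14), Cpt1c (0.25), Ccl4 (1.22, adjusted p = 0.0584), Cdk1 (0.85) and Cfb (0.50).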

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

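The counts of called genes changed with the libraries and the variance model. With protein-coding transcripts only, 181 of the 195 called genes that were tested kept their sign and 71 stayed past the threshold. The counts moved to 4 higher and 0 lower with no filter on low values (29036 genes tested), 35 and 0 without a variance trend, 496 and 64 with array weights, and 680 and 192 at an adjusted p under 0.1. Lower calls alone moved to 27 with a mean TPM of at least 5, to 40 with median-of-ratios scaling and to 3 after removal of mitochondrially encoded genes. The alternatives chosen after seeing the data gave 88 and 3 with protein-coding transcripts only and 388 and 25 with the GC and length correction. Leaving out single libraries gave 3 to 409 higher and 0 to 11 lower. For all of these counts the cause was not tested. The replicate block gave 74 higher and 0 lower. Correlations of deviations between libraries of the same number were 0.03, -0.07 and -0.02, and not every library was closest to its own number. These values show no shared effect of the replicate number, but they cannot tell whether the libraries were paired by design. Gene lists past the threshold numbered 10 to 19 under the other alternatives, but 0 with an estimated correlation and 1 with fry, the immediate early genes. The erythroid list also missed the threshold with a mean TPM of at least 5, without mitochondrially encoded genes, without a variance trend and with array weights (camera adjusted p 0.0576 to 0.0915). Lists that had not passed did so with no filter (regeneration, interferon, satellite glia and Schwann cell genes), without mitochondrially encoded genes (regeneration and interferon), with protein-coding transcripts only (fibroblast and interferon) and with the replicate block (regeneration, camera adjusted p = 0.0150, and interferon, 0.0365). Lep stayed higher throughout (0.72 to 1.499 on leaving out a library).

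Of 37 named genes that were called, 35 lost the call under at least 1 alternative and 12 moved by over 1.5 times, and of 66 that were not, 15 passed under at least 1 and 45 moved by over 1.5 times. Among the named genes and the lists, signs turned for results that had not passed, apart from the cytoskeleton list; with all libraries the largest of these were 0.27 for neutrophil markers, 0.15 for Atf3 and -0.15 for B and plasma cell markers. Under quantile normalization the values were 0.0022 for Stat3 and for the leptin receptor signalling list, -0.034 for endothelial, -0.028 for spinal cord glia, -0.018 for cytokine, 0.036 for heat shock (camera adjusted p = 0.0424), -0.019 for PI3K-mTOR, -0.023 for ion channel, -0.026 for axon guidance, 0.019 for cytoskeleton and -0.048 for cell cycle genes. After removal of mitochondrially encoded genes they were 0.0021 for Stat3, 0.013 for leptin receptor signalling, 0.014 for heat shock and 0.026 for unfolded protein response genes. Array weights gave 0.0070 for leptin receptor signalling, 0.0058 for unfolded protein response, -0.0062 for PI3K-mTOR and -0.0053 for ion channel genes. Median-of-ratios scaling gave -0.014 for PI3K-mTOR, -0.017 for ion channel, -0.0046 for synaptic and -0.0085 for axon guidance genes. A mean TPM of at least 5 gave 0.016 for macrophage and -0.0021 for ion channel genes, and no filter on low values 0.050 for B and plasma cell markers. Protein-coding transcripts only gave 0.0027 for leptin receptor signalling, 0.0046 for pericyte and 0.0030 for unfolded protein response genes. The GC and length correction gave 0.0019 for unfolded protein response, -0.024 for PI3K-mTOR, -0.029 for ion channel, -0.023 for synaptic and -0.023 for axon guidance genes. Leaving out single libraries gave -0.067 to 0.010 for Stat3, -0.11 to 0.32 for Atf3, -0.27 to 0.14 for Sprr1a, and list medians of -0.039 to 0.040 for leptin receptor signalling, -0.024 to 0.10 for large-diameter neurons, -0.18 to 0.12 for macrophages, -0.012 to 0.59 for neutrophils, -0.13 to 0.20 for endothelium, -0.25 to 0.15 for pericytes, -0.042 to 0.016 for heat shock, -0.033 to 0.027 for unfolded protein response, -0.0078 to 0.017 for PI3K-mTOR, -0.037 to 0.016 for ion channel, -0.029 to 0.015 for synaptic, -0.035 to 0.038 for axon guidance and -0.14 to 0.037 for complement genes. Depth is unknown, so its limit on low genes such as Lep cannot be stated.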

Other observations

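Of the tests below, those with protein-coding transcripts only, those with the GC and length correction, and those on splicing factor families, on genes with retained-intron transcripts, on heat shock genes, on other cell types, on erythroid cells and on handling were chosen after the data were seen. Of 7 further long RNA genes picked after seeing their values, with no test of them as a group, 5 rose: Malat1 from 96.1 ± 54.1 to 313 ± 8.39 TPM (log2 fold change 1.83, SE 0.32, limma adjusted p = 0.0466), Snhg14 from 64.0 ± 3.53 to 131 ± 8.61 TPM (1.02, SE 0.06, adjusted p = 0.00349), Rian from 459 ± 71.8 to 768 ± 50.2 TPM (0.75, adjusted p = 0.0285), Firre (1.95, adjusted p = 0.0448) and Ftx (1.09, adjusted p = 0.0393). Meg3 (230 ± 193 and 1227 ± 193 TPM, 2.74, adjusted p = 0.0566) and Neat1 (1.37, adjusted p = 0.0898) did not pass. AAV-GFP replicate 1 stood apart, with Malat1 at 158 TPM against 57.8 and 72.4 and Meg3 at 450 TPM against 85.4 and 155. Without it the adjusted p was 0.00105 for Malat1 and 0.00522 for Meg3. When any other library was left out, Malat1, Rian, Firre and Ftx missed the threshold (Malat1 at 0.154 without AAV-GFP replicate 2), while Snhg14 passed in each of the 6 fits (adjusted p 0.00323 to 0.0454).

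The difference with leptin was larger for retained-intron than for protein-coding transcripts of the same genes. In 3236 genes with a protein-coding transcript and retained-intron transcripts at a mean of at least 1 TPM over all libraries, the median log2 difference was 0.92 for retained-intron transcripts and -0.04 for protein-coding ones, and retained-intron transcripts had the higher difference in 2876 of them (88.9%). A rise with leptin helps a gene to pass that filter: with the filter on the AAV-GFP libraries alone, the medians were 0.60 and -0.04 over 2243 genes, and the difference was higher for retained-intron transcripts in 1856 (82.7%). Of small RNA genes few passed the test: 2 of 45 small nucleolar RNA genes rose (median log2 fold change 1.01), 2 of 27 microRNA genes (0.99) and 0 of 21 small nuclear RNA genes (1.202; 6 higher and 1 lower at an unadjusted limma p under 0.05), with no test of these classes as groups. Of 29 genes lying inside introns on the sense strand 5 rose. Of 69 tested genes of the splicing factor families Srsf, Clk, Luc7l, Rbm and Hnrnp, 9 rose, none fell and 51 lay above 0 (median 0.15, camera p = 6.67e-08, p = 0.247 with an estimated correlation). Examples, also picked after seeing the values, are Clk1 (1.48, adjusted p = 0.0306) and Hnrnph1 (0.59, adjusted p = 0.0200). With protein-coding transcripts only, 2 of these genes rose and the median was 0.06.

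The first pattern weighed is the excess of higher over lower calls, 233 against 10, which was less uneven at an unadjusted p under 0.05, with 1703 higher and 1237 lower. A trend with GC content and transcript length would lose most of the change when corrected, but 97.6% of the median fold change of the called-higher genes was left. Retained-intron or other non-coding transcripts may carry a part of it: with protein-coding transcripts only, 54.9% of the median was left over 185 genes, and 40.6% over the 122 of them with a measured retained-intron transcript. Of the 243 called genes 195 were tested in that fit, and 71 stayed past the threshold, among 88 higher and 3 lower calls. Those 122 genes passed a filter over all libraries that a rise of retained-intron transcripts with leptin helps to pass, so their smaller share may come in part from that choice. Whether more unspliced nuclear RNA entered the libraries made with leptin, by cell state or by preparation, stays open, and the labels give no value that separates these. With 10 splits of the 6 libraries into 3 and 3, only the real split (1 of 10) gave as many calls, 243 against 4 in the highest other split, but 10 splits cannot give a share under 0.05.

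The second pattern is the rise of immediate early genes with Socs3. Non-coding transcripts do not account for it, since 89.9% of the median was left with protein-coding transcripts only. A stress response that raises most heat shock genes would raise their median too, but it was -0.020 against 0.94 for the immediate early genes. Adjusted over the list alone, 2 of the 15 tested heat shock genes rose and 1 fell, so a response that moves only a few of them is not excluded. More glial cells, vascular cells, fibroblasts, macrophages, neutrophils or B cells would raise their markers as much, whereas the highest of those lists, neutrophil markers, had a median of 0.27 (S100a8 0.35, S100a9 0.31; median 0.59 without AAV-GFP replicate 2, where the immediate early median was 0.96). The erythroid median was 1.39 (SD 0.63 over 7 members), above that of the immediate early genes. It lay below that median without AAV-Leptin-GFP replicate 3 alone (0.55, SD 0.32, against 1.03). Leaving out AAV-Leptin-GFP replicate 1 or 2 gave 1.97 or 1.65 against 0.94 or 0.87. The immediate early rise thus did not depend on replicate 3, which had the most haemoglobin. In replicate 1 haemoglobin was 238 TPM, against 256 in AAV-GFP replicate 1. The mean of the immediate early genes exceeded every AAV-GFP library in all 3 AAV-Leptin-GFP libraries, as did that of the erythroid genes. These values go both ways, so they do not decide whether more erythroid cells contributed to the rise. A difference in handling that moves immediate early genes alone cannot be told apart from an effect of leptin on the 15 members that rose, since dissociation itself can induce such genes and any handling that differed by group would run with the treatment.

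The third pattern is the lower level of nuclear oxidative phosphorylation and ribosomal protein genes. The larger mitochondrial share does not account for all of it, as with those genes removed and the rest rescaled the median over both lists was still -0.099. A trend with GC content and transcript length does not account for all of it either, as after correction for both the median was -0.085, with ribosomal protein genes at -0.09 (camera adjusted p = 2.2e-07) and oxidative phosphorylation genes at -0.08 (camera adjusted p = 4.31e-06). That correction left expression level as it was, and a trend with length and expression level together could account for the pattern: random lists matched on both had a median of -0.131 (5th to 95th percentile -0.142 to -0.119), and the real median of -0.133 stood at percentile 45.2 of 10000. Counts of gene lists are a weak guide in these data, since 3 of the 10 splits, the real one included, gave as many lists past the threshold, 15 in the real split and up to 17 in another.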
